A study of Rattus norvegicus with 2 samples.

How the data were processed

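The series held 2 libraries of dissociated rat lung cells, 1 of control animals and 1 of animals exposed to a gas explosion. Per the labels' protocols, lungs were digested with enzymes, red cells were lysed, dead cells were removed, and libraries were made with 10x Chromium 3' chemistry and sequenced on an Illumina NovaSeq. The labels do not say how many animals went into a library. The deposited matrices hold whole-number UMI counts per gene and barcode, not normalized; per the file headers they were written by cellranger 7.1.0. The submitters' processing notes name bcl2fastq 2.20, Cell Ranger 6.1.1 and the builds mRatBN7.2 and rn6, with no role for either build. The annotation used for counting is not given in the sources used here. The matrices list 42172 genes and hold only barcodes called as cells, so droplets without cells were not used here. Gene neighbours and older symbols were looked up in a table of assembly GRCr8, for names only.

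Cells with at least 200 genes and at most 25% of UMIs from mitochondrial genes were kept, which removed 21 and 16 control and 192 and 22 explosion barcodes. No mitochondrial protein-coding gene had a UMI in either library, so the mitochondrial share rests on mt-Rnr1 and mt-Rnr2. Doublets were called per library with Scrublet (scanpy 1.11.5, expected doublet rate set in proportion to the number of cells) and removed: 1786 control cells (8.47%) and 631 explosion cells (5.07%). Counts were scaled to 10000 per cell and logged. For clustering, 2000 variable genes chosen per library without mitochondrial, ribosomal, hemoglobin and immunoglobulin genes, 30 principal components, 15 neighbours and Leiden at resolution 1 (python-igraph 0.11.9, 10 iterations, seed 1) were used, with both libraries together and no batch integration. A neighbour pair needed at least 2 shared neighbours.

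Clusters were named from 215 markers of 21 classes, of which 213 were found. A marker counted as detected when its mean per 10000 UMIs (0.2 added) was at least 2-fold that of clusters of other first-pass classes and at least 5% of the cluster's cells held a UMI. A name needed at least 3 detected markers, and a cluster stayed unnamed when its top 10 genes held more markers of another class or 3 cycling genes. This naming procedure was settled after the clusters were seen, and other references for the marker fold were tried. The rule that kept cluster 25, led by Il1rl1 and Gata3, out of the T-like class was also added then; it held 0.497% of the control and 1.6% of the explosion cells. Clusters 2, 22, 25, 26 and 32 stayed unnamed. Cluster 2 had the leading genes Nos2, Mal, Pou2f2 and Il1b.

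UMIs were summed per library and class. CPM is a gene's sum over the sum of all genes in the class and library, and ratios are explosion over control, with the exact conditional interval of the ratio of 2 Poisson counts at the 95% level. Shares have exact Clopper-Pearson intervals. A count of 0 was given as the limit that 3 counts allow. Classes with at least 200 cells in both libraries were compared: macrophage, T, mesothelial, monocyte, B, secretory, NK and ciliated. For 27 gene lists fixed before the data were examined, together with the markers, the rule for named genes and the first group of other settings, the median log2 ratio was taken over members with at least 10 UMIs, with 0.5 counts added to each sum and at least 4 members. Its percentile came from 10000 random lists of the same size matched in 20 expression bins, and its interval from 2000 draws of the counts. Of 533 genes named in the lists, 494 were found in the files. The class median was taken over genes with at least 20 UMIs in both libraries.

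Genes were named by a fixed rule. In the 5 classes with the most cells in their smaller library, the rule took the 6 highest and 6 lowest ratios among genes with a symbol, at least 50 CPM and 30 UMIs in the library where the gene was higher, an interval that excluded 1.5-fold, and a CPM there of at least 0.5 times that of the library's other cells. Mitochondrial, ribosomal protein, hemoglobin, immunoglobulin and T cell receptor genes and markers of other classes were left out. The rule also took up to 10 genes per direction with the largest smallest change over all compared classes, and for each list described the 2 highest and 2 lowest members with at least 30 UMIs in a library. Examples were taken from these. The values of 1 list member are not reported here, although it stayed in its list's median. The 5 genes given as shares of cells with a UMI, from cells thinned to 500 UMIs, and the clusters compared alone were chosen after their values were seen.

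The median depth within a class was 5802.5 control and 1118.5 explosion UMIs for macrophage-like, 1826 and 420.0 for T-like, 2146.5 and 793 for mesothelial-like, 1589 and 656.5 for monocyte-like, 1159 and 320.0 for B-like, 11441 and 1393 for secretory-like, 1619.5 and 577 for NK-like and 4833.5 and 852.5 for ciliated-like cells. The share of free RNA, estimated from markers of other classes, was 6.80% to 18.7% in control and 8.26% to 30.6% in the explosion library. Its profile was taken as the sum of the library's kept cells, as droplets without cells were not used.

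The calculations were tested on simulated data, in a test written after the comparison had first been run. Counts were drawn from the real means with 200 changed genes and with 100 lists of 15 genes. The intervals covered the true ratio for 97.6% of 20619 genes in macrophage-like, 97.7% of 16583 in T-like, 97.2% of 17763 in mesothelial-like, 97.7% of 16288 in monocyte-like and 97.8% of 14978 in B-like cells. A 4-fold change was recovered for 100%, 99%, 100%, 100% and 85% of the changed genes in these classes, and a 2-fold change for 97%, 52%, 65%, 61% and 32%. Unchanged genes passed the 1.5-fold limit in 0% of cases, or 0.0625% in B-like cells. Unchanged lists fell outside the limits in 4%, 4%, 1%, 5% and 9% of cases, and lists changed 2-fold lay above them in 100%. Both simulated libraries were drawn from a pooled profile of the class, so unchanged genes differed by counting error only. In the real data, the log2 ratios of genes had an SD of 0.93 in B-like up to 1.04 in macrophage-like cells. The simulated rates therefore hold for counting error and do not carry over to the real lists.

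Each result was recomputed with other settings, of which the first group, fixed beforehand, was at least 500 genes per cell, at most 10% mitochondrial UMIs, doublets kept, each library clustered alone, resolution 2, a median-ratio size factor, a total without mitochondrial, ribosomal protein and hemoglobin genes, thinning to 500 UMIs before summing, subtraction of free RNA, list members with at least 50 UMIs, and 1 CPM added in place of counts. Settings chosen after the data had been seen were at least 500 UMIs in both libraries, cluster 2 counted as monocyte-like, cluster 8 alone, cluster 12 against cluster 2, macrophage-like cells without cluster 24, a total without the secretoglobins Scgb1a1, Scgb3a1 and Scgb3a2, ratios minus the median over the other classes, and other references for the marker folds. Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.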

Results

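Dissociated lung cells from rats exposed to a gas explosion and from control rats were profiled by droplet-based single-cell RNA sequencing, to see how the cells of the lung varied after the blast. Each group had 1 library, so the differences between the groups have no replicate check and no test was run. Intervals in parentheses are 95% intervals and cover counting error only. The control library held 21117 barcodes and 139486248 unique molecular identifiers (UMIs), with a median of 4917 UMIs and 1827 genes per barcode. The explosion library held 12642 barcodes and 9017416 UMIs, with a median of 538.5 UMIs and 422 genes per barcode. The shallowest barcode carried 500 UMIs in the control library and 231 in the explosion library. After the cell filters and removal of called doublets, 19298 control cells with a median of 4687 UMIs and 11811 explosion cells with a median of 532 UMIs were kept. Among the kept cells, 5563 of the explosion library and 0 of the control library had fewer than 500 UMIs.

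The RNA content of the libraries also differed. Scgb1a1, the main secretory protein of club cells, took 24.1% of the control UMIs and 5.94% of the explosion UMIs. Ribosomal protein genes took 11.2% and 5.99%, the mitochondrial ribosomal RNAs 0.677% and 3.59%, and Rn45s, the ribosomal RNA precursor, 0.00880% and 0.304%. Hemoglobin genes took 0.0332% and 0.0328%. The cells fell into 33 clusters, of which 28 could be named from marker genes, giving 13 classes. The class names were rebuilt here and mean cells like the named type. In 22 of the 33 clusters, more than 80% of the cells came from 1 library, so a cluster here may stand for a library rather than a cell type.

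The first comparison asked how the cellular makeup of the lung differed after the explosion. Macrophage-like cells made up 45.8% (45.1 to 46.5, exact binomial intervals) of the control cells and 16.6% (15.9 to 17.3) of the explosion cells. Secretory-like airway cells made up 15.4% and 6.02%, ciliated-like cells 5.43% and 2.46%, and cells like type 1 alveolar epithelium, the thin cells of the gas exchange surface, 0.762% (147 cells) and 0.0593% (7 cells). Neutrophil-like cells were 305 in control and 18 after the explosion, or 1.58% (1.41 to 1.77) and 0.152% (0.0903 to 0.241). Shares were higher in the explosion library for fibroblast-like cells, at 0.575% (0.473 to 0.692) against 3.62% (3.29 to 3.98), and for NK-like cells, at 2.39% against 4.40%. T-like cells made up 6.91% (6.55 to 7.27) and 11.3% (10.8 to 11.9), B-like cells 4.25% and 6.51%, monocyte-like cells 6.46% and 8.09%, and mesothelial-like cells, which line the lung surface, 6.23% and 8.71%. The type 2 alveolar-like share was 0.829% in control and 0.821% after the explosion. Control neutrophil-like and type 1 alveolar-like cells were shallow, at medians of 774 and 1123 UMIs against 4687 over all kept control cells. Type 2 alveolar-like control cells, whose share was level, had a median of 767. Whether shallow cells of some classes were missed in the explosion library was not tested.

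By compartment, named immune cells made up 67.4% (66.8 to 68.1) of the control and 47.1% (46.2 to 48.0) of the explosion cells, and epithelial cells 22.4% (21.8 to 23.0) and 9.36% (8.84 to 9.90). Endothelial cells, all blood endothelial-like, made up 0.814% (0.692 to 0.951) and 1.92% (1.68 to 2.19), and stromal cells 6.80% (6.45 to 7.17) and 12.3% (11.7 to 12.9). Among the 13014 control and 5561 explosion cells named as immune, macrophage-like cells took 68.0% and 35.2%, T-like cells 10.2% and 24.1%, B-like cells 6.31% and 13.8%, NK-like cells 3.55% and 9.35%, monocyte-like cells 9.58% and 17.2%, and neutrophil-like cells 2.34% and 0.324%. Cluster 2, with 36 control and 2888 explosion cells and a median of 334 UMIs in the explosion library, stayed unnamed, and unnamed cells made up 2.53% and 29.3%. Its best class was monocyte and the class that competed for its name was neutrophil, both immune, so the named immune cells leave it out. With it counted, immune cells made up 67.6% of the control and 71.5% of the explosion cells. Counting cluster 2 as monocyte-like turned the immune difference from -20.4 to 3.91 percentage points and raised the monocyte-like difference from 1.63 to 25.9, with an explosion share of 32.5%. The explosion monocyte-like share was likewise 32.5% with at most 10% mitochondrial UMIs, 32.2% with doublets kept and 25.9% at resolution 2. With cluster 2 counted, the shares of immune cells in control and explosion were 67.8% and 23.2% for macrophage-like, 10.2% and 15.8% for T-like, 6.29% and 9.10% for B-like, 3.54% and 6.15% for NK-like and 9.83% and 45.5% for monocyte-like cells.

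Red cells and dead cells had been removed before capture, the libraries started from different UMI minima, and with at least 500 UMIs per cell in both, the T-like and B-like differences of 4.42 and 2.26 points became -0.84 and -3.15, while the macrophage-like difference of -29.2 points became -17.7. In that setting the mesothelial-like difference went from 2.48 to 8.27, the monocyte-like one from 1.63 to 4.93, the secretory-like one from -9.38 to -4.85 and the ciliated-like one from -2.98 to -1.65. Among immune cells, T-like cells then took 10.2% and 11.7%, and B-like cells 6.31% and 2.12%, so the B-like rise reversed there too. With marker folds taken over the mean of other clusters, a setting chosen after the data were seen, the macrophage-like shares were 14.7% and 16.1%, a difference of 1.37 points in the other direction. Unnamed cells then made up 39.1% of the control and 30.4% of the explosion cells, against 2.53% and 29.3% in the main setting. This reversal thus came with many control cells losing their name.

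**Figure D1:**
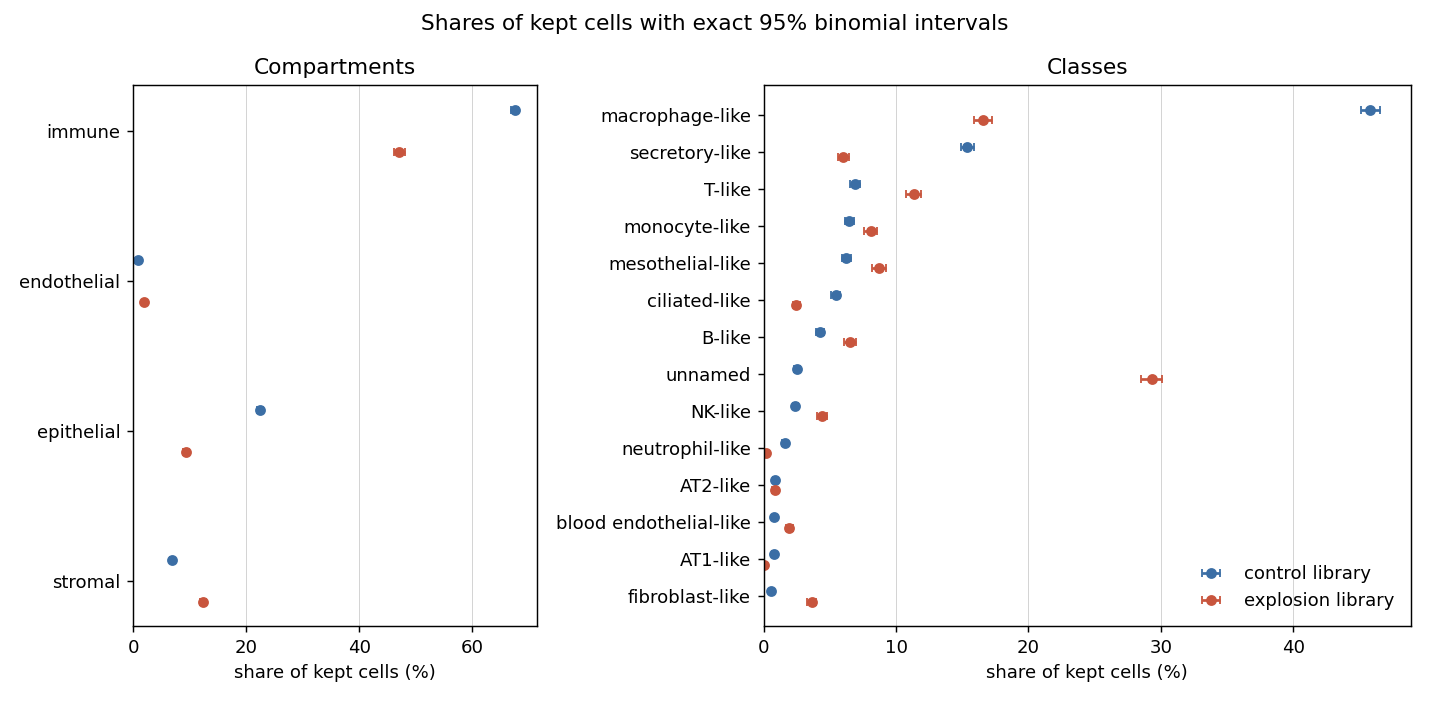
Share of kept cells (%) per compartment (left) and per class (right) in the control and explosion libraries; dots are the shares, bars the exact 95% binomial intervals, counting error only. The macrophage-like share was 45.8% in control and 16.6% after the explosion, and unnamed cells made up 2.53% and 29.3%.

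Expression was then compared within the 8 classes that had at least 200 cells in both libraries. Components of the mitochondrial respiratory chain were lower in the explosion library in every compared class, and Rn45s was higher in every one. The log2 ratio of CPM (UMIs of a gene scaled by the total of its class and library), explosion over control, had a median over classes of 4.51 for Rn45s, with a range of 3.93 to 4.93. Of the other 9 genes with the largest smallest ratio over the 8 classes, among those with at least 50 CPM and 30 UMIs in each, Papolg, a poly(A) polymerase, had a median of 3.73, the insulin gene Ins2 3.60, and Ttc39a 5.60. The remaining 6 were the chromatin regulators Kmt2d (2.58), Srcap (2.38) and Baz1b (2.16), with Zbed6 (2.32), the splicing factor Prpf38b (2.29) and the RNA helicase Ddx3x (2.21). Genes with fewer UMIs in a class, such as RT1-CE1, were also higher in all 8. Within the same limits, 8 genes were lower in all 8 classes. They were the complex I subunits Ndufa13 (-1.87, range -2.41 to -1.57) and Ndufb11 (-1.48), the complex III subunit Uqcr10 (-1.36), the ATP synthase subunits Atp5f1e (-1.61), Atp5pf (-1.58) and Atp5pd (-1.56), the redox protein Park7 (-1.69) and the histone H2aj (-1.57).

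Among genes with at least 20 UMIs in both libraries, the median log2 CPM ratio lay above 0 in each class. It ran from 0.54 in monocyte-like cells to 1.64 in secretory-like cells. The explosion sums were smaller, so this limit favours genes that were higher there and can itself raise the median. List values are given relative to it, as the class median or median of all genes, while folds of single genes are plain CPM ratios. A count of members below it is thus not by itself a drop. The comparison with random lists does not use it. A small fold above 1 can therefore lie below the median gene of its class. On the relative scale the list of nuclear-encoded oxidative phosphorylation genes lay between -2.39 in ciliated-like and -1.33 in NK-like cells, and its CPM medians were below 0 in all 8 classes too. In macrophage-like cells 32 of 32 members lay below the class median, with a list median of -1.94. Cox7a2, a subunit of cytochrome c oxidase, was 5.09-fold lower there (4.29 to 6.07), 5.48-fold lower in T-like cells (3.58 to 8.83) and 12.2-fold lower in monocyte-like cells (6.90 to 23.7). Across 1605 genes measured in all 8 classes, the ratios of any pair of classes had a Spearman rho between 0.743 and 0.937, with a median of 0.856 over 28 pairs. Genes are not independent replicates. The mean of a gene over the classes held 89.7% of the variance of these ratios.

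Of the 27 gene lists fixed beforehand, 26 gave a value in at least 1 class, and 201 list medians were measured over the 8 classes. Against 10000 random lists matched on size and expression, as a description of these libraries, 26 medians lay above the outer 5% limits, 28 below and 147 within. Extracellular matrix and fibrosis genes lay above the limits in 7 classes, endothelial junction genes in 5, complement in 4, macrophage wound repair genes in 3 (and below in 2), endothelial activation and coagulation genes in 2, proliferation genes in 2 and the interferon response in 1. The MHC class II list lay above in 2 classes and below in 1. Besides oxidative phosphorylation, below in 8, the hemoglobin and erythroid list lay below in 7 classes, with values of -2.75 to -0.83 over all 8, although its CPM median in secretory-like cells was 0.01. With members at 0 UMIs set to 3 counts, its CPM medians were 0.44 in secretory-like and 0.27 in ciliated-like cells, the latter against -0.71 otherwise. Glycolysis lay below in 4 classes, with values of -1.67 to -0.39 over all 8, while its CPM median in secretory-like cells was above 0, at 0.37 against a relative value of -1.27. Hypoxia response genes lay below in 3 classes and NRF2 oxidative stress targets in 1, and in ciliated-like cells both flipped with the scaling: 0.14 by CPM against -1.05 for hypoxia, and 0.04 against -1.15 for NRF2. Iron handling and ferroptosis lay below in 1 class, at -1.22 in ciliated-like cells, where its CPM median of -0.03 became 0.59 with the member at 0 UMIs set to 3 counts, and cytotoxic genes in 1.

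Many stress programs did not stand apart from random lists in any of the 8 compared classes. Those classes leave out the unnamed cluster 2, which held 2888 explosion cells and has Nos2 and Il1b among its leading genes. The inflammatory cytokine and NF-kB list lay within the limits in 8 of 8 classes, with values of -0.42 to 0.13 relative to the class median. So did the inflammasome list (-0.64 to 0.40), heat shock (-1.27 to -0.21), immediate early and dissociation genes (-0.92 to 0.08), the unfolded protein response (-0.84 to -0.06) and p53 targets (-0.72 to -0.07). Surfactant genes (-0.54 to -0.11), the alveolar transition and injury list (-0.97 to -0.03), neutrophil alarmins (-0.98 to -0.24) and nuclear-retained RNAs (-0.02 to 0.28) were also within the limits in 8 of 8 classes. Type 2 alveolar-like, type 1 alveolar-like and neutrophil-like cells were too few to compare, at 97, 7 and 18 explosion cells. The surfactant, alveolar and alarmin lists were thus not measured in those cells. Platelet genes were measured only in macrophage-like cells and lay within the limits there (-0.84). The mitochondrially encoded list had no value, because the files list no UMI for any mitochondrial protein-coding gene.

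**Figure D2:**
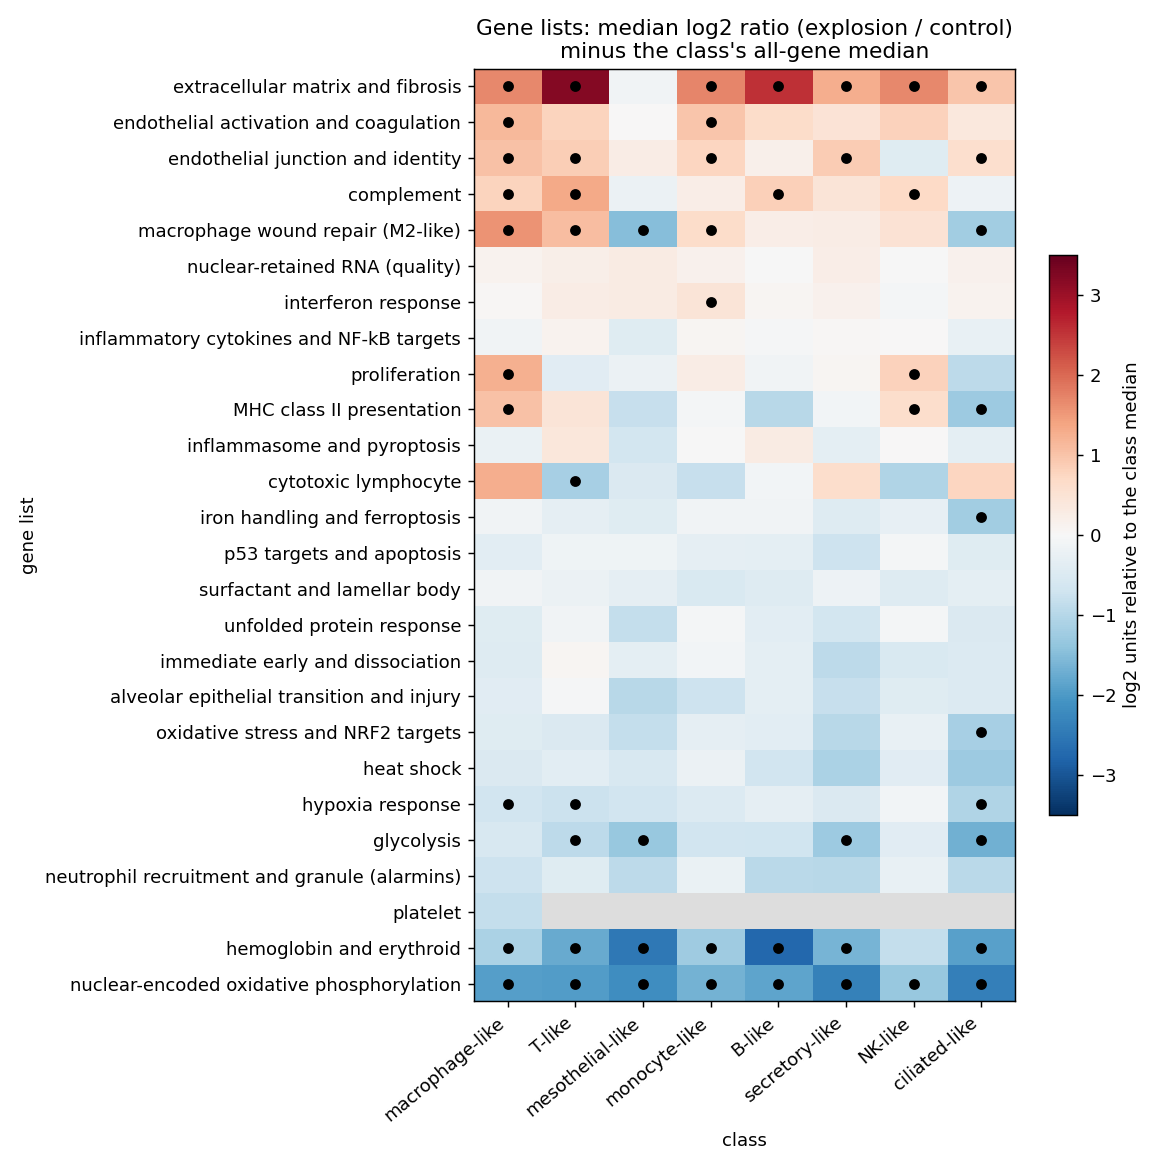
Heat map of the median log2 CPM ratio (explosion over control) of each gene list minus the median of all genes, for 26 lists (vertical axis) and 8 classes (horizontal axis); black dots mark medians outside the outer 5% of 10000 matched random lists, and grey squares had too few members. Oxidative phosphorylation lay below 0 in all 8 classes, while glycolysis in secretory-like cells and hypoxia and NRF2 targets in ciliated-like cells lay below 0 here but above 0 by CPM alone.

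In macrophage-like cells, wound repair, proliferation and matrix genes were higher in the explosion library relative to other genes. Spp1, the secreted phosphoprotein osteopontin, was 10.8-fold higher (9.96 to 11.8). Ltc4s, the leukotriene C4 synthase, was 6.50-fold lower (5.24 to 8.16), and Ftl1, the ferritin light chain, 5.21-fold lower (4.97 to 5.46). Control cells of this class came mostly from clusters 1 and 3 (5845 and 2225 cells) and explosion cells from cluster 5 (1680 cells), and 126 control and 174 explosion cells came from the C1qa-led cluster 24. The highest ratios under the naming rule belonged to Ttc39a, 48.2-fold (40.5 to 57.6), Rn45s, 30.2-fold, RT1-CE1, an MHC class I gene, 26.0-fold (22.0 to 30.7), Ins2, 19.4-fold (16.7 to 22.4), and Papolg, 13.6-fold. That rule asks for at least 50 CPM and leaves out markers of other classes, here and in the classes below. Next to Ltc4s and Ftl1, the lowest under that rule were Dstnl1, 14.3-fold lower (9.94 to 21.3), Ndufa13, 5.35-fold lower (4.51 to 6.39), Cox7a2 and Borcs8, 4.72-fold lower.

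The wound repair list in macrophage-like cells had a median of 2.22 (1.87 to 2.76), 1.56 above the class median, with 16 of 20 members above it. Stab1, a scavenger receptor, was 27.2-fold higher (17.1 to 43.5) and Cd163, the hemoglobin scavenger receptor, 21.3-fold higher (14.8 to 30.5), while Trem2 was 4.35-fold lower (3.44 to 5.57) and Fabp5 1.96-fold lower (1.80 to 2.15). Cd163 is among the leading genes of cluster 24 and Trem2 of cluster 3. Without cluster 24, the list median was 1.18, or 0.54 above the median of that class, and Tgm2 was 7.35-fold (6.60 to 8.17) and Spp1 11.2-fold higher (10.3 to 12.2). After thinning to 500 UMIs, 1.12% of control and 6.20% of explosion cells held an Spp1 UMI (0.910 to 1.36 and 5.12 to 7.44), and 203 shallower explosion cells were left out. In B-like cells, which should lack it, 0.122% and 4.35% (0.906 to 12.2, 69 cells) did. Without thinning, the shares were 3.93% and 8.72%, at median depths of 5802.5 and 1118.5 UMIs, against 0.244% and 1.30% in B-like cells at 1159 and 320.0 UMIs. Cd163 was found in 0.124% and 0.854% of thinned macrophage-like cells (0.328% and 1.79% unthinned), against 0 of 821 and 0 of 69 B-like cells, which allows up to 0.365% and 4.35%, so at equal depth 69 B-like cells were too few to tell the explosion shares of Cd163 and Spp1 apart from free RNA. Unthinned, Cd163 was found in 1 of 821 and 0 of 769 B-like cells, which allows up to 0.390% in the latter, at a lower depth than that of macrophage-like cells.

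Proliferation genes had a median 1.25 above that of macrophage-like cells, with 17 of 22 members above it. The replication helicase subunits Mcm5 and Mcm6 were 9.82-fold (6.71 to 14.1) and 7.19-fold higher (5.90 to 8.73), and the histone variant H2az1 was 2.02-fold lower (1.84 to 2.21). The MHC class II list lay 1.02 above the class median, with 9 of 15 members above it, led by the invariant chain Cd74 at 7.69-fold (7.1 to 8.31) and RT1-Ba at 7.1-fold (6.01 to 8.37), while RT1-DMa was 1.65-fold lower (1.46 to 1.88). That list was within the random limits without cluster 24 (0.35 above), and it reversed when cells were thinned to equal depth, from a median of 1.68 to -0.31. Matrix genes (19 of 23 members above, 1.68 above the class median), complement (13 of 18, 0.78), endothelial junction genes (15 of 18, 1.01) and endothelial activation genes (12 of 17, 1.14) were also above the limits. Col1a1, the main fibroblast collagen, was 15.2-fold higher (11.7 to 19.6), with 165 and 99 UMIs, beside a fibroblast-like share of 0.575% in control and 3.62% after the explosion. The complement proteases C1r and C1s were 16.7-fold (11.3 to 24.5) and 11.8-fold higher (7.16 to 18.9), and the adhesion factor Vwf, the leading gene of the blood endothelial-like cluster, 5.05-fold higher (2.76 to 8.71). Relative to the same genes in the other classes, the endothelial activation median was -0.011. Hypoxia genes were split, with 7 of 21 members above the class median and 14 below (list value -0.67). The growth factor Vegfa was 13.6-fold (8.21 to 22.2) and the hexokinase Hk2 5.51-fold higher (3.98 to 7.52), whereas Mif was 3.16-fold (2.69 to 3.74) and the phosphofructokinase Pfkp 3.02-fold lower (2.76 to 3.31).

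In monocyte-like cells of the explosion library, interferon-stimulated genes and the inducible enzymes Nos2, which makes nitric oxide, and Acod1, which makes itaconate, were higher. Nos2 was 99.0-fold higher (37.6 to 370, from 4 control and 108 explosion UMIs) and Acod1 49.5-fold higher (18.3 to 188, from 4 and 54). Thbs1, the matrix protein thrombospondin, was 18.7-fold higher (11.7 to 31.0). Control cells of this class came mostly from cluster 12 (942 cells, against 4 of the explosion library) and explosion cells from cluster 8 (952 cells, against 305 of control). The unnamed cluster 2 shares the leading genes Mal, Pou2f2, Treml4 and Gngt2 with cluster 12, and Mal, Il1b and Mefv with cluster 8. Class ratios may therefore partly compare different subsets. Of the 12 genes named by rule for this class, 11 kept their direction in cluster 8 alone and 12 with cluster 12 against cluster 2. The interferon response list had a median of 1.00 (0.66 to 1.36), or 0.46 above the class median (0.11 to 0.77), with 19 of 29 members above it. After thinning, it lay 0.15 above (-0.021 to 0.89). Cxcl10, a T cell chemoattractant, was 11.9-fold (8.16 to 17.7) and Ifi44 7.79-fold higher (4.18 to 15.1), while Bst2 was 1.77-fold (1.51 to 2.09) and Ifi27 1.58-fold lower (1.4 to 1.79).

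Within cluster 8 alone the interferon list median was 1.98 (1.82 to 2.51), 1.42 above the cluster's all-gene median, with 19 of 24 members above it. The mix of cells there differed between the libraries: 163 of 305 control and 244 of 952 explosion cells took another name at resolution 2, and the MHC class II list lay at -1.07, with 13 of 15 members below the median. The guanylate-binding protein Gbp2 was 17.6-fold higher there (10.9 to 30.3), Ifi44 26.0-fold (6.66 to 223), Cxcl10 10.8-fold (6.47 to 19.1), the transcription factor Irf1 6.67-fold (5.06 to 8.92) and Nos2 82.6-fold (22.3 to 691, from 2 and 108 UMIs). Bst2, at a ratio of 0.745 (0.618 to 0.896), and Ifi27, at 0.830 (0.721 to 0.955), were lower, and Isg15, at 1.46 (0.764 to 2.78), was not told apart from 1. The genes named in cluster 8 other than Gbp2, Ifi44, Bst2 and Ifi27 were picked after their values were seen. Among thinned monocyte-like cells, a Nos2 UMI was found in 1 of 1247 control cells (0.0802%) and 42 of 712 explosion cells (5.90%, 4.28 to 7.89), with 244 shallower explosion cells left out and 0 of 821 and 0 of 69 B-like cells, which allows up to 0.365% and 4.35%, a limit inside the explosion interval. Unthinned shares were 0.241% and 6.69%, at median depths of 1589 and 656.5 UMIs, against 0 of 821 and 7 of 769 B-like cells (0.910%, 0.367 to 1.87), at 1159 and 320.0 UMIs. Cxcl10 was found in 0.561% and 4.78% of the thinned cells (1.12% and 6.59% unthinned), against 0.122% and 0 of 69 B-like cells (0.365% and 0.260% unthinned). Gbp2 was found in 3.53% and 12.1% (11.6% and 16.9% unthinned), against 1.83% and 4.19% of thinned mesothelial-like cells (10.7% and 7.29% unthinned, at 2146.5 and 793 UMIs).

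**Figure D3:**
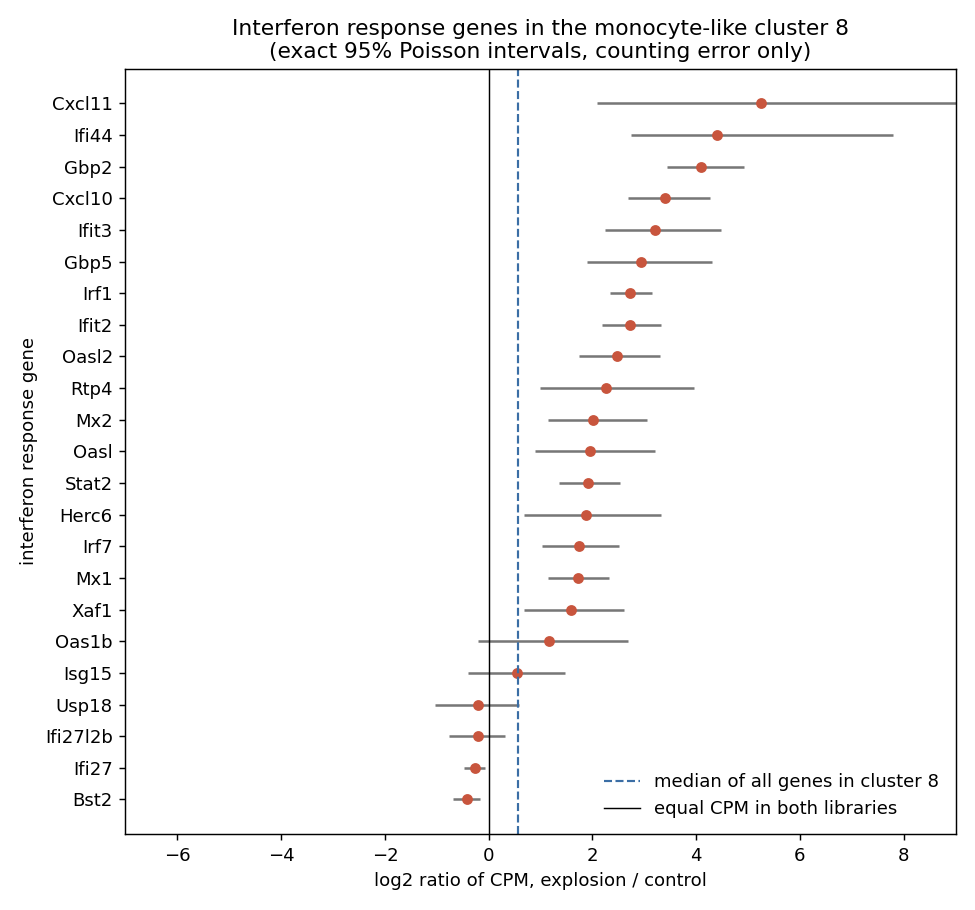
Log2 CPM ratio (explosion over control) of interferon response genes reported for cluster 8, a monocyte-like cluster held by both libraries; points are genes with 0.5 counts added, lines exact 95% intervals of the ratio of Poisson counts (the upper limit of Cxcl11 lies off the axis), and the dashed line is the median of all genes in the cluster (0.57). Gbp2 and Irf1 lay above that median, and Ifi27 and Bst2 below it.

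The other genes with the highest ratios under the naming rule in monocyte-like cells were the inhibitory receptor Lilrb3, 57.4-fold higher (18.5 to 288, from 3 and 47 UMIs), Ttc39a, 50.5-fold, and Rn45s, 24.4-fold. The lowest ratios under that rule belonged to Ankrd33b, 23.3-fold lower (6.36 to 194), the defensin Defb14, 22.0-fold (10.6 to 55.0), Dstnl1, 20.3-fold, the muscle enolase Eno3, 13.4-fold (7.01 to 29.6), Cox7a2, and Sirpd, 12-fold. With doublets kept, the direction of Ankrd33b turned, at a log2 ratio of 0.22. Defb14 is a leading gene of cluster 12, and within cluster 8 its log2 ratio was 0.85. Wound repair genes lay 0.65 above the class median with 10 of 17 members above it; Lyve1 was 3.85-fold higher (2.89 to 5.13) and Trem2 12.3-fold lower (2.09 to 495). Endothelial activation genes lay 0.96 above, with Thbs1 and the anticoagulant receptor Thbd, 3.14-fold higher (2.56 to 3.85), leading, and Icam2 1.53-fold lower (1.15 to 2.06). Matrix genes (1.72 above) and endothelial junction genes (0.74 above) stood apart as well. Relative to the same genes in the other classes, the wound repair, endothelial activation and matrix medians became -0.57, -0.15 and -0.066.

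In T-like cells, cytotoxic genes were lower in the explosion library, with 14 of 16 members below the class median and a list median of -0.39 (-0.98 to -0.18), or -1.16 relative to it. The chemokine Ccl5 was 11.2-fold lower (9.47 to 13.5) and the granzyme Gzmk 6.23-fold lower (3.34 to 13.2), whereas the transcription factor Tbx21 was 2.48-fold higher (1.35 to 4.44). Perforin, Prf1, 1.52-fold higher by CPM (1.14 to 2.02), lay below the class median of 0.76 on the log2 scale. Control T-like cells came mostly from cluster 6 (1286 cells) and explosion cells from cluster 7 (1284 cells), and Ccl5, Gzmk and Prf1 are leading genes of the NK-like clusters. When each library was clustered alone the cytotoxic median became 1.05 and the Gzmk ratio 0.31, so their direction depended on how the cells were clustered. The highest ratios under the naming rule were those of Ttc39a, 181-fold (91.0 to 424), Zfp536, with 0 and 32 UMIs and a log2 ratio of at least 5.49 with control set to 3 counts (the exact interval starts at 5.11), the secreted prokineticin Prok2, 33.8-fold (12 to 131), RT1-CE1, 25.6-fold, Rn45s, 19.8-fold, and Vps9d1, 15.2-fold (8.45 to 29.0). Under that rule, which leaves out Ccl5 as a marker of another class, the lowest besides Gzmk and Cox7a2 were the mitochondrial ribosomal proteins Mrpl58, 8.22-fold lower (3.71 to 22.7), and Mrpl41, 7.64-fold lower (2.91 to 28.5), with Selenoh, 5.15-fold, and the mitochondrial iron-sulfur protein Cisd3, 5.11-fold. Glycolysis genes lay at -0.92 relative to the class median, with 12 of 14 members below it, and Ldha, lactate dehydrogenase, was 1.76-fold lower (1.46 to 2.15). Hypoxia genes lay at -0.76, with a CPM median of 0.00.

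Complement genes in T-like cells lay 1.31 above the class median with 17 of 17 members above it, C1r at 30.4-fold (11.9 to 99.2) and C4a at 8.52-fold higher (6.70 to 10.9). Matrix genes lay 3.23 above, with Fn1 27.7-fold (12.4 to 72.8) and Col1a1 26.6-fold higher (14.7 to 52.1, from 13 and 82 UMIs), and endothelial junction genes 0.87 above. C4a leads the mesothelial-like clusters and Col1a1 marks fibroblasts, and the mesothelial-like and fibroblast-like shares were higher in the explosion library. The estimated share of free RNA in T-like cells was 13.2% in control and 21.7% in the explosion library. Wound repair genes lay 1.07 above (11 of 13 members), with Lpl, a leading gene of the macrophage-like cluster 5, 6.23-fold higher (3.47 to 11.4), but their median of 1.84 turned to -0.27 when called doublets were kept.

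In NK-like cells, held mostly by cluster 14 in both libraries (439 and 436 cells), proliferation genes lay 0.80 above the class median, with 15 of 22 members above it. Mcm5 was 14.2-fold (5.92 to 41.2) and Mcm6 7.19-fold higher (4.48 to 11.9), while Ube2c was 2.12-fold (1.28 to 3.67) and H2az1 2.24-fold lower (1.99 to 2.54). The MHC class II list lay 0.61 above, with RT1-Da 3.54-fold higher (2.18 to 5.83), but its median of 1.16 turned to -3.39 after free RNA was subtracted. Complement (0.69 above, turning from 1.24 to -0.052 with doublets kept) and matrix genes (1.67 above) stood apart too. Relative to the same genes in the other classes, the NK-like matrix median became -0.32. In B-like cells (cluster 15 in control, 791 cells, and cluster 16 after the explosion, 759 cells), RT1-Bb, an MHC class II chain, was 9.44-fold lower (6.78 to 13.5), and Slfn4, a member of the interferon-inducible schlafen family, was 14.2-fold higher (10.4 to 19.8). RT1-CE1 was 49.5-fold higher (15.8 to 250), Ttc39a 34.5-fold, Rn45s 16.9-fold, Gstcd 15.4-fold and Ins2 12.5-fold. Clec4m, 25.7-fold (4.50 to 1025), Bola1, 20.4-fold (3.56 to 818), Aprt, 14.3-fold (4.79 to 70.0), Dstnl1, 11.7-fold (3.15 to 98.5), and Med29, 8.29-fold lower (2.2 to 70.0), held 1 to 3 explosion UMIs each, and with at least 500 genes per cell the log2 ratio of Med29 was 0.17. Matrix genes lay 2.57 above the B-like median (Col1a1 22.9-fold, 11.3 to 52.7, from 9 and 57 UMIs) and complement 0.84 above (C4a 8.34-fold, 5.85 to 12.1), beside an estimated share of free RNA of 17.6% in control and 30.6% in the explosion library, the highest explosion share of the 8 classes.

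In mesothelial-like cells, glycolysis and macrophage wound repair genes were lower in the explosion library. Glycolysis had a median of -0.73 (-1.06 to -0.53), or -1.34 relative to the class, with 14 of 15 members below the class median, Pfkp 4.26-fold (2.77 to 6.88) and Ldha 3.53-fold lower (2.78 to 4.54). Wound repair genes lay at -1.49, with the mannose receptor Mrc1 4.47-fold lower (3.28 to 6.26) and the transglutaminase Tgm2 3.72-fold higher (3.09 to 4.48), beside a macrophage-like share of 45.8% in control and 16.6% after the explosion. Control cells came mostly from cluster 9 (1044 cells) and explosion cells from cluster 11 (955 cells). The highest ratios under the naming rule were those of Rn28s, a ribosomal RNA, 217-fold (37.4 to 8734, from 1 and 55 UMIs), Ttc39a, 84.2-fold, Cep295nl, 22.7-fold (12.2 to 46.1), Rn45s, 15.2-fold, Ccdc152, 14.9-fold, and RT1-CE1, 14.2-fold (9.71 to 21.1). The lowest under that rule were Slurp1, a secreted ligand of nicotinic receptors, 24.8-fold lower (9.59 to 91.3), Dstnl1, 19.5-fold, Plac9, 13.2-fold (5.07 to 48.8), RT1-CE2, 10.8-fold (4.55 to 33.6), Mrpl43, 9.82-fold, and the elastase Cela3b, 8.99-fold (5.49 to 15.8). Cela3b is a leading gene of cluster 28, and its ratio turned to 1.86 on the log2 scale when doublets were kept.

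In the airway epithelium, antioxidant, iron and energy genes were lower in ciliated-like cells relative to other genes. The metallothionein Mt1 was 13.0-fold lower (3.59 to 107, from 974 and 2 UMIs), thioredoxin, Txn1, 3.70-fold (2.91 to 4.78), Ftl1 7.95-fold (4.81 to 14.2) and haptoglobin, Hp, 4.41-fold (2.82 to 7.33). Glycolysis there lay at -1.67, with Gapdh 2.75-fold lower (1.92 to 4.09), and MHC class II and wound repair genes at -1.27 and -1.22. By CPM their medians were near 0, at -0.083 (5 members higher, 6 lower) and -0.030, the latter 0.020 with the members at 0 UMIs set to 3 counts. Matrix genes lay 0.96 and endothelial junction genes 0.58 above, but the matrix median became -0.10 relative to the same genes in the other classes. In secretory-like cells, matrix genes lay 1.26 and endothelial junction genes 0.90 above the class median, and glycolysis 1.27 below it but 0.37 above 0 by CPM, with Pfkp 6.83-fold (2.33 to 33.2) and Gapdh 1.63-fold lower (1.31 to 2.06). Ciliated-like control cells came mostly from cluster 13 (889 cells) and explosion cells from cluster 19 (277 cells); secretory-like control cells came from clusters 4 and 10 (1938 and 990 cells) and explosion cells from cluster 17 (608 cells).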

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

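No paired analysis was possible because each group had 1 library, and no library could be left out. Settings called added were chosen after the data had been seen, and the others were planned. Values are explosion minus control in percentage points for shares and log2 ratios or list medians otherwise, with the reported value of shares and lists in brackets at first mention. Of 44 list medians, 27 kept their direction in all their settings, as did 62 of 78 gene ratios, 10 of 14 class shares, 3 of 4 compartment shares and 5 of 5 shares of cells with a UMI. The list medians were those outside the random limits with a CPM interval that excluded 0. The gene ratios were those named by rule, which took the largest changes. These counts therefore do not speak for other lists or genes. Of the 675 alternative list medians, 483 stayed within the counting error of the reported value, 174 moved beyond it and 18 reversed; of 1027 gene ratios, 842, 167 and 18; of 140 class shares, 83, 49 and 8; of 40 compartment shares, 17, 19 and 4; of 5 shares with a UMI, 3, 2 and 0. Subtraction of free RNA gave a value for 37 of the 44 list medians and the minimum of 50 UMIs for 43. The cause was not tested for any shift, unless it is named.

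Cell filters. With at least 500 UMIs in both libraries (added), which removed only explosion cells, B-like cells were at -3.15 [2.26], T-like -0.84 [4.42], macrophage-like -17.7 [-29.2], endothelial 0.515 [1.11], epithelial -6.89 [-13.1], immune -15.5 [-20.4] and stromal 12.2 [5.53]; also counting cluster 2 as monocyte-like (added) gave immune -10.4 and left the other values as they were. With at least 500 genes, B-like cells were at -3.14, T-like -4.52, macrophage-like -12.3, endothelial 0.256, epithelial -6.09, immune -12.9, stromal 13.9, Med29 in B-like cells 0.17, the cytotoxic list in T-like cells -0.16 [-0.39] and wound repair in macrophage-like cells 1.53 [2.22]. With at most 10% mitochondrial UMIs, the immune difference was 3.70 and the monocyte-like interferon list 1.54 [1.00]. With doublets kept, macrophage-like cells were at -24.8, epithelial -15.1 and immune 6.43, Ankrd33b in monocyte-like cells 0.22, Cela3b in mesothelial-like cells 1.86, complement in NK-like cells -0.052 [1.24], the cytotoxic list -0.14, interferon 1.79, and wound repair in T-like cells -0.27 [1.84].

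Clustering and names. With cluster 2 counted as monocyte-like (added), the immune difference was 3.91. Each library clustered alone gave macrophage-like -27.7, epithelial -14.0, immune -18.7, stromal 4.41, Gzmk in T-like cells 0.31 and the cytotoxic list 1.05. Resolution 2 gave immune -0.52. Marker folds over the mean of other clusters (added) gave macrophage-like 1.37, unnamed -8.71 [26.8], immune 15.1, Cela3b 1.39, Defb14 0.85, interferon 1.98 and wound repair in macrophage-like cells 1.5; folds over the median of clusters (added) gave epithelial -18.3 and stromal 10.9. Cluster 8 alone (added) gave Defb14 0.85 and interferon 1.98, cluster 12 against cluster 2 (added) interferon 1.38, and macrophage-like cells without cluster 24 (added) wound repair 1.18.

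Scaling, depth and free RNA. The median-ratio size factor gave -1.16 for the cytotoxic list in T-like cells, -1.27 [0.37] for glycolysis in secretory-like cells, 0.46 for interferon, 1.56 for wound repair in macrophage-like cells and -1.94 [-1.28] for oxidative phosphorylation there, which is the shift of the class median. A total without the 3 secretoglobins (added) gave glycolysis in secretory-like cells -0.39, and a total without mitochondrial, ribosomal protein and hemoglobin genes gave oxidative phosphorylation -1.37. Thinning gave -0.31 [1.68] for MHC class II in macrophage-like cells and 0.56 for interferon. Free RNA subtraction gave -3.39 [1.16] for MHC class II in NK-like cells.

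Ratios minus the median over the other classes (added), which remove what all classes share by construction, turned Ccdc152 (-0.48), RT1-CE1 (-0.29), Rn28s (-0.42) and Rn45s (-0.60) in mesothelial-like cells, Cox7a2 (0.018), Dstnl1 (0.31) and Ttc39a (-0.018) in macrophage-like cells, Dstnl1 (0.89), Rn45s (-0.45) and Ttc39a (-0.54) in B-like cells and Rn45s (-0.23) in T-like cells. The same setting turned endothelial activation in macrophage-like (-0.011) and monocyte-like cells (-0.15), matrix genes in NK-like (-0.32), ciliated-like (-0.10) and monocyte-like cells (-0.066), hemoglobin in macrophage-like (0.16) and monocyte-like cells (0.23), wound repair in monocyte-like cells (-0.57) and oxidative phosphorylation in NK-like (0.40), secretory-like (0.40) and monocyte-like cells (0.0026). Without reversal it gave the cytotoxic list -1.70, interferon 0.25, wound repair in macrophage-like cells 0.70 and oxidative phosphorylation there -0.18. Among the 8 compared classes, the explosion B-like cells had the lowest median depth, 320.0 UMIs, and 69 of them reached 500.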

Other observations

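Bpifa1 and Scgb3a1 had few UMIs in the explosion library, while Scgb1a1 was lower there but still made up 5.94% of its UMIs, against 24.1% in control. Over all kept cells, Bpifa1, an antimicrobial protein of the airway lining, had 27568 control UMIs and 16 explosion UMIs, and the secretoglobin Scgb3a1 had 1179455 and 925. In macrophage-like cells, Scgb3a1 stood at 566 CPM in control and 11.5 CPM after the explosion, and Scgb1a1 at 16210.0 and 4826 CPM. Cluster 10, led by Bpifa1, Scgb3a1 and Muc5b, held 990 control and 40 explosion cells (5.13%, 4.82 to 5.45, and 0.339%, 0.242 to 0.461). Cluster 10 is defined by these genes, so its size is not a result apart from them. These genes were chosen after their values were seen.

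Among the unnamed cells, cluster 26, led by Siglech and Irf8, genes of plasmacytoid dendritic cells, made up 0.233% (0.170 to 0.312) of control and 1.85% (1.61 to 2.10) of explosion cells. Cluster 25, led by Il1rl1, Gata3 and Il2ra, genes of type 2 lymphocytes, made up 0.497% and 1.6%. Cluster 32, led by Calca, Chga and Trpm5, genes of neuroendocrine and tuft cells, held 87 and 15 cells, and the cycling cluster 22, led by Stmn1 and Mki67, 1.16% and 1.28%. In macrophage-like cells, Nos2 had 41 control and 45 explosion UMIs, a 27.7-fold higher CPM (17.8 to 43.4). Over all kept cells, Il1b was 6.06-fold (5.84 to 6.29) and Irf1 6.29-fold higher (5.92 to 6.69), while Tnf, at 1.2-fold (1.04 to 1.39), lay below the median of all genes (1.07 on the log2 scale). Cluster 2 has Nos2 and Il1b among its leading genes and makes up 24.5% of the explosion cells. These genes were chosen after their values were seen.

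Of the tests of 3 patterns that follow, those on correlations between classes, on the shift shared by all classes and on the RT1-CE1 and RT1-CE2 pair were chosen after the result was seen. The first pattern is the low level of nuclear-encoded oxidative phosphorylation genes in the explosion library in 8 of 8 classes. With all cells thinned to 500 UMIs, the list stayed more than 0.5 below the class median in 7 of 8 classes. The exception was B-like cells (-0.36), of which 69 explosion cells were deep enough. The pattern in the 7 classes was thus not confined to cells under 500 UMIs. Thinning at random keeps each gene's expected share of a cell's UMIs, so it cannot exclude depth as a cause. After subtraction of free RNA, the list also stayed more than 0.5 below the class median in 8 of 8 classes (-2.42 to -1.25). The profile subtracted was the sum of the library's kept cells, which share the drop, so this cannot exclude free RNA either. A difference between the library preparations may be the cause and cannot be told apart from a response shared by all cell types, because each group had 1 preparation: the median rho of 0.856 between classes fits both.

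The second pattern is the higher level of interferon response genes in monocyte-like cells. Within cluster 8, another mix of subsets is argued against by cells also monocyte-like at resolution 2 (142 control and 708 explosion cells). There the list lay 1.81 (1.36 to 2.24) above the median of all genes. After subtraction of free RNA, the value in cluster 8 was 1.42 (1.24 to 2.03). The profile subtracted was the sum of the library's kept cells, so free RNA of another makeup is not excluded. Removing each gene's median over the other classes left 1.27 (0.91 to 1.44) in cluster 8. This argues against the shift shared by all classes there. Thinning gave 2.40 (2.04 to 3.25) in cluster 8 but, as above, cannot exclude depth as a cause. In the whole class the value was 0.25 (-0.010 to 0.49) after removal of the shared shift, so that shift is not excluded there. Thinning gave 0.15 (-0.021 to 0.89) in the whole class. As thinning cannot decide on depth, depth is excluded neither in cluster 8 nor in the class as a whole. What raised these genes stays open, as differences between the animals, and in how long cells waited before capture, were not tested.

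The third pattern is the exchange of MHC class I genes, with RT1-CE1 higher and RT1-CE2 lower in the explosion library in 8 of 8 classes, although the interval of RT1-CE2 included 1 in B-like and ciliated-like cells. Over all kept cells, RT1-CE1 made up 13.8% (12.7 to 14.9) of the UMIs of the pair in control and 89.9% (88.2 to 91.4) after the explosion. The median of 8 other genes of MHC class I presentation, such as B2m, Tap1 and Nlrc5, lay more than 0.5 above the class median in 0 classes (-1.20 to -0.02). This argues against a rise of these genes beyond that of the median gene. The class medians themselves lay above 0 by CPM, so a rise of these genes by plain CPM is not excluded. Over all kept cells, the SD of log2 ratios over the 26 other RT1 class I genes was 1.31, against 1.44 for the median random list (27.6th percentile). The mix of classes can also spread random lists there, so this cannot decide on a variant or read sharing across the family. Within classes, RT1-A1 (down to -2.04), RT1-A3 (-1.72 to -0.46), RT1-CE4 (-0.83 to -0.35) and RT1-CE16 (-1.74 to -0.95) lay below the class median in 8 of 8. RT1-A2 (0.17 to 1.26) and RT1-N3 (0.048 to 2.12) lay above it in 8 of 8. The RT1-CE1 share of the pair was more than 50 percentage points higher in 8 of 8 classes, which restates the exchange and does not bear on its cause. A variant or read sharing in the pair, alone or with such members, may be the cause. A regulated switch cannot be told apart from it, because the strain and alleles of the animals are not given in the sources used here.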
